A study of Populus tremula x Populus alba with 39 samples.

How the data were processed

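RNA from the lowest part of stem cuttings was copied to double-stranded cDNA, labelled with Cy3 and hybridized to one-colour NimbleGen poplar arrays, with 1 cutting per array and 39 arrays in 8 groups (2 genotypes at 4 times). The scanner files hold intensity per probe on a linear scale, extracted with NimbleScan 2.4.31 per the file headers. The deposited value table holds log2 signal that the authors quantile normalized across the arrays. Its column medians lie between 8.1771 and 8.1787, and it ranks the probes of each array as the scanner signal does (Spearman 1). Its background step is not stated.

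The analysis started from the scanner intensity. In R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), the signal was background corrected (normexp, offset 50) without regard to group. The log2 values of 55793 gene model probes were then quantile normalized. A second series of 12084 probes, whose identifiers start with G, and 4196 random-sequence control probes were kept apart. A probe counted as above background on an array when it exceeded the 95th percentile of the random controls there. Scanner values reach a ceiling of 65535 units, which 3 to 82 probes per array had reached. The deposited table was used as an alternative.

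One mean per group was fitted in limma with 1 shared spread per probe, moderated by eBayes. Two-sided p values were adjusted by Benjamini and Hochberg over all gene model probes, and a probe was called at an adjusted p under 0.05. The comparisons were DDK against NT at each time, their mean over times, each later time against 0 h in each genotype, and the genotype by time interaction. The comparisons, tests and main alternatives were chosen before the data were examined. Errors are SDs between arrays or SEs of fitted differences. Where 1 or more arrays on the lower side of a named difference did not exceed the controls, the fold is given as a lower bound, with each signal on that side raised at least to the weakest one counted as above background on its array. Such a bound allows for background only, not for the spread between arrays, so other fits can fall below it. The analysis was tested on simulated data, with the real spread of each probe but independent normal noise on each array. These data held no lot, day or array-wide structure, so recovery in the real arrays may differ. With changes planted in 50 probes per size, the averaged comparison recovered 44%, 90%, 100% and 100% at log2 0.5, 1, 2 and 4. The comparison at 24 h recovered 2%, 42%, 94% and 100%.

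The rule for named features, fixed in advance, took genes by name. No file or table used here pairs probes with genes, so its fallback was used: the 2 largest rises and the 2 largest falls per comparison, by identifier, with the averaged comparison limited to probes of 1 sign at all times. For the same reason the lists of hormone, stress, wall, cell cycle and cell type marker genes fixed in advance could not be run, and the probe of the transgene was not identified. Genotype labels could therefore not be checked independently. The 2 probes that part the genotypes were found through these same labels, so they show only whether a single array departs from its group.

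The labels do not number the replicates, so numbers here follow the chip order within a group and pair nothing. Groups came from the sample titles. Chip lot (8 lots) here means the leading part of the chip number, as no label names a lot. Extraction day (4 days) means the day of image extraction dated in the file headers, not of RNA extraction. The alternatives were no background correction, median centring, the deposited table, a filter that kept 40518 probes above the controls on at least 4 arrays, variance trend with robust estimation, ordinary analysis of variance, array weights, lot as a random or fixed block, the compared groups alone, and leaving out each array. Extraction day as a block, fits within a day, the share of probes above controls as a covariate, and leaving out arrays with under 50% of probes above controls were added after seeing the data. So were the comparisons of successive times.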

Results

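Gene expression was measured at the base of leafy stem cuttings of 1 clone of a hybrid poplar, Populus tremula x P. alba, in the hours after the cutting was taken from its mother plant. One genotype was non-transgenic (NT). The other was a single transgenic line (DDK) that expresses ΔDDKPtRR13, a constitutively active form of PtRR13. PtRR13 is a type-B response regulator, a transcription factor of the cytokinin signalling pathway. The series asks whether PtRR13 holds back the formation of adventitious roots, the roots that arise from stem tissue. The lowest 5 mm of each cutting was taken at 0, 6, 24 and 48 h, and each array read 1 cutting. There were 5 arrays in each of the 8 groups except DDK 0 h, which had 4, giving 39 in all. Each array read 55793 gene model probes, and the number of arrays per group limits the precision. Nothing in the files used here pairs a probe with a gene name, so features are named by probe identifier, without a function or a genome position.

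The median scanner signal ran from 213.67 to 1397.78 units per array. Between 43.7% and 65.2% of the gene model probes read above the random-sequence control probes of their array. The mean share was 60.8% ± 4.19 (SD, n = 5) in NT 0 h, 57.9% ± 4.49 in NT 6 h, 49.1% ± 5.82 in NT 24 h and 56.5% ± 5.55 in NT 48 h. In DDK it was 59.3% ± 3.77 (n = 4), 58.5% ± 5.24, 56.8% ± 2.14 and 55.6% ± 5.39 at the same times. The share was under 50% on 4 arrays, which were NT 24 h replicates 1, 2 and 5 and NT 48 h replicate 4. Arrays of 1 group correlated with each other at a median r of 0.949 across probes. The first principal component held 48.0% of the variance and parted the 0 h arrays from all later ones.

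**Figure D1:**
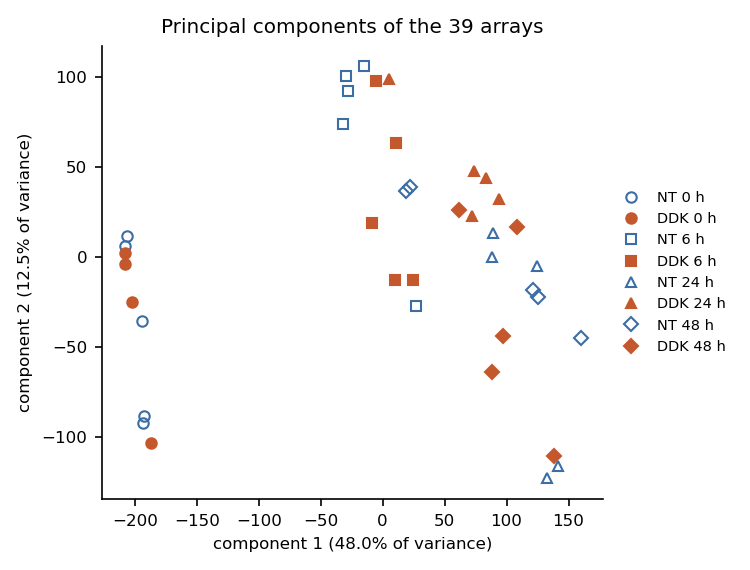
Principal components 1 (horizontal, 48.0% of variance) and 2 (vertical, 12.5%) of the 39 arrays, in the units of the log2 data; each point is 1 array, with symbols for time and filled symbols for DDK. The 0 h arrays lie between -208.2 and -186.7 on component 1, and every later array lies to their right, from -32.3 upward.

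The first question was how the stem base of non-transgenic cuttings changed after excision. No uncut stem was sampled at the later times, so excision cannot be told apart from other changes since 0 h. The excision response here means the change against 0 h. After 6 h, 13960 probes (25.0% of those tested) had changed against 0 h, 6400 upward and 7560 downward. A change of at least 4-fold was seen in 1816 of the rises and 1478 of the falls. The 2 largest rises were of E_POPLARS26062P182428, from a log2 signal of 7.48 ± 0.41 to 15.37 ± 0.28 (SD, n = 5 each), and E_POPLARS13972P097803, from 7.48 ± 0.16 to 15.16 ± 0.17. The latter was not above the control probes on any 0 h array, so its rise was at least 135-fold. The former rose by 7.89 on the log2 scale (SE 0.27, limma adjusted p = 3.26e-24), in all 5 arrays, and was above the controls on 1 of the 5 arrays at 0 h, so its rise was at least 154-fold. The 2 largest falls were of E_POPLARS21523P150655, at least 106-fold, and E_POPLARS05767P040364, at least 59.0-fold. At 6 h the former was above the controls on 1 of 5 arrays and the latter on 4.

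After 24 h the response of the non-transgenic stem base was wider, with 22959 probes (41.2%) changed, 10697 upward and 12262 downward. The largest rises were of E_POPLARS39579P277050, at least 169-fold, and E_POPLARS40553P283868, at least 161-fold. Both were above the control probes on 0 of 5 arrays at 0 h and stood at 15.48 ± 0.23 and 15.41 ± 0.13 (SD, n = 5) on the log2 scale at 24 h. Both had already reached 13.19 ± 0.56 and 13.30 ± 0.46 at 6 h. The largest falls were of E_POPLARS21523P150655, at least 74.3-fold lower, and E_POPLARS22689P158820, at least 77.6-fold lower. The latter stood at 15.08 ± 0.27 at 0 h, 11.69 ± 0.48 at 6 h and 7.66 ± 0.19 at 24 h.

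After 48 h, 20607 probes (36.9%) differed from 0 h in the non-transgenic cuttings, 9673 upward and 10934 downward. The leading rises were the 2 probes of 24 h, E_POPLARS40553P283868 at least 200.4-fold and E_POPLARS39579P277050 at least 173-fold. E_POPLARS21523P150655 stayed low, at least 64.9-fold below 0 h (limma adjusted p = 6.67e-13) and above the controls on 2 of 5 arrays. E_POPLARS01423P009956 was at least 53.4-fold lower, going from 14.06 ± 0.13 at 0 h to 7.29 ± 0.41 at 48 h (SD, n = 5). Of the 6400 probes raised at 6 h, 4391 were raised at 24 h as well, where independent lists would share 1227. Of the 7560 lowered at 6 h, 6381 were lowered at 24 h, against 1661 for independent lists. These lists share their 0 h arrays. With 0 h replicates 1 and 2 as the controls of one list and the others as those of the second, the lists shared 3335 rises and 4461 falls, against 745 and 1126 for independent lists.

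The non-transgenic counts were 15715, 24941 and 22336 at 6, 24 and 48 h with chip lot as a block, and 14493, 25278 and 19228 with image extraction day as a block. Within extraction day 2 they were 10804 at 6 h and 18477 at 24 h, and within day 3 they were 9476, 17000 and 16320 at 6, 24 and 48 h. Median centring in place of quantile normalization gave 59.5%, 57.5% and 56.6% upward at 6, 24 and 48 h, in place of 45.8%, 46.6% and 46.9%. Over all gene model probes, called or not, it moved the changes upward by a median log2 of 0.18, 0.04 and 0.14. No weight is therefore put on which direction was the more frequent, while the named changes kept their direction.

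The second question was how the cuttings with active PtRR13 respond to the same excision. In DDK 14152 probes changed by 6 h, 6132 upward and 8020 downward. At 24 h 16873 had changed, 8239 upward and 8634 downward, and at 48 h 18507, 8023 upward and 10484 downward. The probes that led the non-transgenic response moved here too. E_POPLARS26062P182428 went from 7.56 ± 0.28 (SD, n = 4) at 0 h to 15.01 ± 0.29 (n = 5) at 6 h. E_POPLARS39579P277050 went from 7.05 ± 0.32 to 13.92 ± 0.36 at 6 h and 15.23 ± 0.42 at 24 h. E_POPLARS21523P150655 went from 15.23 ± 0.42 to 8.09 ± 0.50 at 6 h. E_POPLARS22689P158820 went from 15.20 ± 0.25 to 10.94 ± 0.62 at 6 h and 8.36 ± 0.98 at 24 h.

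The DDK counts were 15797, 17421 and 18961 at 6, 24 and 48 h with chip lot as a block, and 14293, 15800 and 18793 with extraction day as a block. Within day 2 they were 10816, 7828 and 14526, from 2 arrays at 0 h and 4, 1 and 3 at the later times. Within day 3, where DDK has 1 array at 0 h and none at 6 h, they were 7715 at 24 h and 9497 at 48 h. A group with 1 array was taken to vary like the others. Median centring gave 62.8% upward at 24 h in place of 48.8%, with a median upward shift of 0.20 (log2) over all gene model probes.

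**Figure D2:**
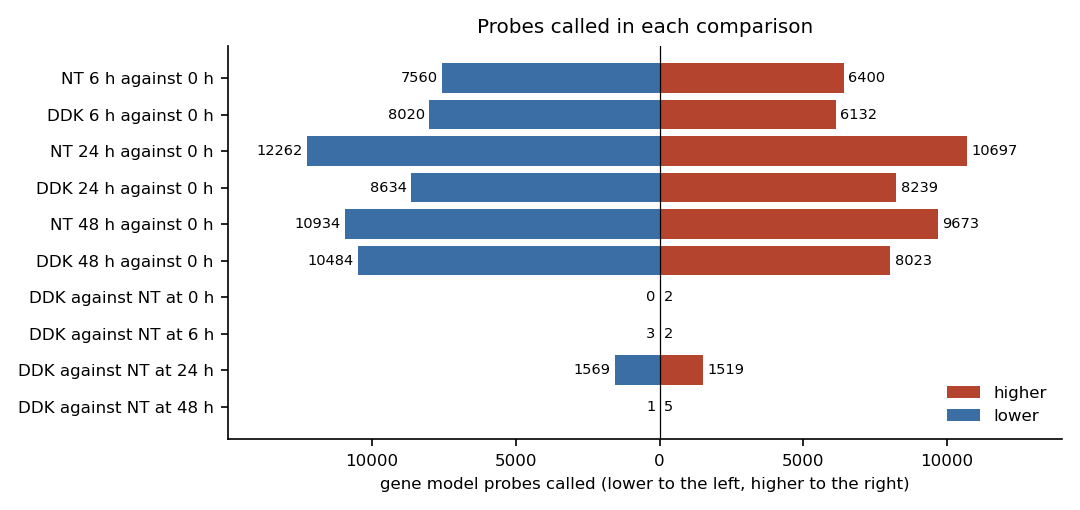
Number of gene model probes called in each comparison (horizontal axis), with probes higher in the first-named group to the right and lower ones to the left. The time comparisons hold 13960 to 22959 probes, while the comparisons of DDK with NT hold 2, 5, 3088 and 6 at 0, 6, 24 and 48 h.

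The excision responses of the genotypes were much alike in direction. Across probes, the changes against 0 h in NT and DDK correlated at r = 0.926 at 6 h, 0.907 at 24 h and 0.941 at 48 h, with jackknife SDs over arrays of 0.07, 0.06 and 0.04. Probes are not independent replicates, so no p is given. Of the probes called in NT, 99.2%, 92.6% and 98.5% had the same sign in DDK at the 3 times. At 6 h 11508 probes were called in the same direction in both genotypes and 0 in opposite directions. At 24 h these counts were 14144 and 10, and at 48 h 15697 and 2. Independent lists would share 1790, 3477 and 3446 probes. Of the NT calls, 82.4%, 61.6% and 76.2% were called in the same direction in DDK at 6, 24 and 48 h. At 24 h 8805 probes were called in NT only and 2719 in DDK only, and at 48 h 4908 and 2808. A call in 1 genotype only is not a test of a difference between them.

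A direct test asked whether any probe responded differently over time in the genotypes. The limma F test of genotype by time called 0 of 55793 probes, with 8923 at an unadjusted p under 0.05. Chance alone would put a share of 0.05 of all probes there on average, and 8923 lies above that share. The count of 0 therefore does not show that no probe responded differently. Array weights gave 276, no background correction gave 1, leaving out NT 6 h replicate 2 gave 3 and leaving out NT 0 h replicate 5 gave 1. Tested singly, the change by 6 h and the change by 48 h gave 0 probes each (1151 and 1826 at an unadjusted p under 0.05). The change by 24 h gave 1 (5964 unadjusted), E_POPLARS37314P261192. This probe fell in both genotypes, from 11.89 ± 0.49 (SD, n = 5) to 8.25 ± 0.36 (n = 5) in NT and from 10.47 ± 0.22 (n = 4) to 9.01 ± 0.42 (n = 5) in DDK. The fall in DDK was smaller by 2.17 on the log2 scale (SE 0.36, limma adjusted p = 0.0274). NT at 24 h was above the controls on 1 of 5 arrays, which bounds the difference at 1.51 or more. It was chosen after its values were seen, and the call was lost when any of 11 of its 19 arrays was left out, with adjusted p up to 0.158. These were NT 0 h replicates 1 and 4, DDK 0 h replicates 2, 3 and 4, NT 24 h replicates 1, 2, 4 and 5 and DDK 24 h replicates 1 and 4, with differences of 2.05 to 2.23. With chip lot as a block the difference was 1.76 (limma adjusted p = 0.121), and with extraction day as a block it was 2.12 (0.0367).

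The central question was which transcripts differ between DDK and NT whatever the time. With 1 transgenic line and no vector control, effects of active PtRR13 cannot be told apart from those of the insertion or of transformation. Averaged over the 4 times, 18 probes differed between DDK and NT, 9 higher and 9 lower in DDK, and 15 of these had the same sign at every time. A pair of probes stood far above the rest and was called at each of the 4 times. E_POPLARS38388P268712 was at least 20.6-fold higher in DDK (fitted log2 4.69, SE 0.19, limma adjusted p = 8.34e-20). Its fitted log2 differences were 3.98, 5.66, 4.43 and 4.71 at 0, 6, 24 and 48 h. In NT it was above the controls on only 1, 2, 2 and 2 of 5 arrays at these times, so its folds are given as lower bounds and its log2 differences, here and below, are fitted values limited by background. All 19 DDK arrays read above all 20 NT arrays on it, with 11.59 as the lowest in DDK and 10.29 as the highest in NT. E_POPLARS01092P007640 had a fitted log2 difference of 3.52 on average (SE 0.22, limma adjusted p = 6.23e-14), and of 2.97, 4.17, 3.51 and 3.45 at the 4 times. It read 15.40 or more on every DDK array and 13.17 or less on every NT array except NT 0 h replicate 5, which read 15.92. On this probe the scanner signal was saturated on that array and on 1 of 5 DDK 6 h arrays, and on no other. Many other DDK arrays read near the scanner ceiling on it, so its fitted differences and folds, here and below, may be too small. Without NT 0 h replicate 5 its difference at 0 h was 3.74 and that of E_POPLARS38388P268712 was 4.50.

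Among the probes lower in DDK at every time, the largest averaged differences were those of E_POPLARS37760P264314, with a log2 of -1.76 (SE 0.23, at least 3.26-fold, limma adjusted p = 4.79e-05), and E_POPLARS16408P114853, with -1.08 (SE 0.18, limma adjusted p = 0.0029). E_POPLARS37760P264314 stood at 10.15 ± 0.80, 9.10 ± 0.71, 12.09 ± 0.60 and 11.75 ± 1.37 (SD, n = 5) in NT at 0, 6, 24 and 48 h. In DDK it stood at 8.35 ± 0.13 (n = 4), 8.55 ± 0.61, 9.62 ± 0.63 and 9.53 ± 0.57. A second probe of the same number, G_POPLARS37760P264318, had a log2 of 0.07 (limma adjusted p = 0.926) and correlated with it over arrays at r = 0.203. For E_POPLARS27813P194689, also among the 18 with -0.84, the second probe G_POPLARS27813P194686 had -0.82 (limma adjusted p = 0.085) and r = 0.935. The median r of all such pairs was 0.712. E_POPLARS28539P199773, named after its values were seen, was at least 1.84-fold higher in DDK on average (fitted log2 1.32, SE 0.12, limma adjusted p = 6.43e-09), with 7 of 20 NT arrays above the controls. Its means in DDK were 8.38 ± 0.27, 9.25 ± 0.42, 10.04 ± 0.27 and 9.85 ± 0.39 over the 4 times, while in NT they lay between 7.87 ± 0.30 and 8.17 ± 0.42. Of the 18 probes, 7 were called at no single time.

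With chip lot as a block 9 probes were called on average and with extraction day as a block 8, while array weights gave 34. The count was 10 without NT 24 h replicate 3. It was 11 without any of NT 0 h replicate 1, DDK 0 h replicate 1, DDK 0 h replicate 4, DDK 6 h replicate 2 or NT 6 h replicate 5. E_POPLARS16408P114853 was not called with extraction day as a block (limma adjusted p = 0.0501). The same was true without the 4 arrays with under 50% of probes above the controls (limma adjusted p = 0.0692).

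**Figure D3:**
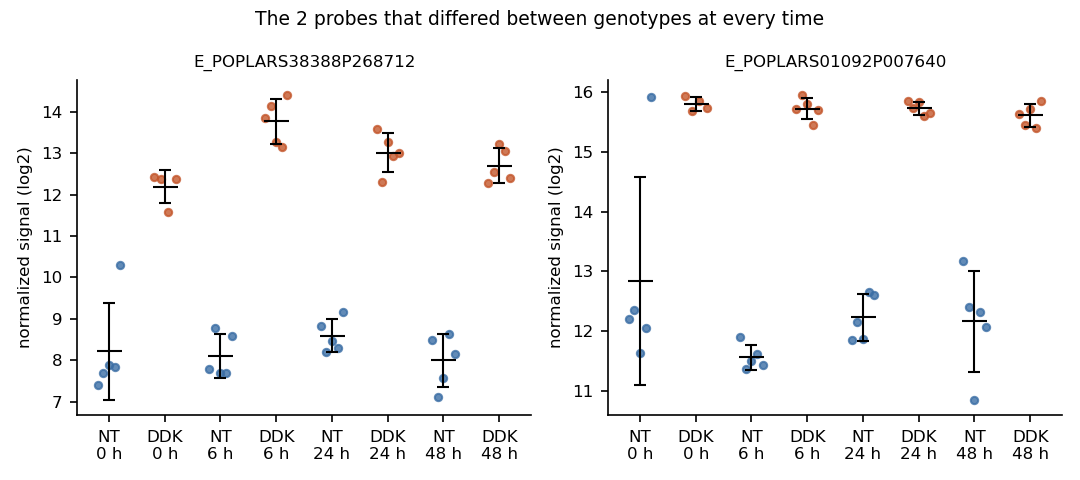
Normalized log2 signal (vertical axis) of the 2 probes that differed between genotypes at every time, in each of the 8 groups; points are arrays, bars the mean and SD. On E_POPLARS38388P268712 every DDK array, from 11.59 up, lies above every NT array, up to 10.29; on E_POPLARS01092P007640 1 NT 0 h array, at 15.92, lies among the DDK arrays.

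At 0 h, before any response to excision, those 2 probes were the only ones called (548 at an unadjusted p under 0.05), both higher in DDK. Chance alone would give a share of 0.05 of all probes on average, and 548 lies below that share. E_POPLARS38388P268712 was at least 12.4-fold higher (SE 0.40 in log2, limma adjusted p = 2.77e-07). E_POPLARS01092P007640 was 7.83-fold higher as fitted (SE 0.46, limma adjusted p = 0.00351). The count was 5 without NT 0 h replicate 2, 3 with chip lot as a block, 2 with extraction day as a block, 11 with array weights and 0 with the compared groups fitted alone. Within extraction day 2 (3 NT, 2 DDK) both probes were called, at fitted log2 differences of 4.75 and 3.75. Within day 3 (2 NT, 1 DDK), with NT 0 h replicate 5 in it, they differed by 2.52 and 1.86 and 0 probes were called by limma.

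At 6 h, 5 probes differed, 2 higher and 3 lower in DDK (2931 at an unadjusted p under 0.05). The higher ones were E_POPLARS38388P268712, at least 42.4-fold (SE 0.38 in log2), and E_POPLARS01092P007640, 18.02-fold as fitted (SE 0.43), with 1 of the 5 DDK arrays saturated. Of the lower ones, E_POPLARS35193P246347 had risen to 10.62 ± 1.27 (SD, n = 5) in NT and to 8.56 ± 0.63 in DDK, a log2 difference of -2.06 (SE 0.37, limma adjusted p = 0.0239) and at least 3.84-fold, as 4 of 5 DDK arrays were above the controls. E_POPLARS02357P016499 was at least 2.23-fold lower (limma adjusted p = 0.00912), at 9.36 ± 1.04 in NT and not above the controls in any DDK array. E_POPLARS04022P028153, named after its values were seen, differed by -1.42 (SE 0.23, limma adjusted p = 0.00811), at least 2.46-fold, with 2 of 5 DDK arrays above the controls.

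The 3 lower calls at 6 h rest on few arrays. E_POPLARS35193P246347 was lost without any of NT 6 h replicates 1, 3, 4 and 5 and DDK 6 h replicates 1 and 4, with differences of -2.12 to -1.77 and limma adjusted p up to 0.30. E_POPLARS02357P016499 was lost without NT 6 h replicate 3, 4 or 5 (-1.71 to -1.64, limma adjusted p up to 0.11), and E_POPLARS04022P028153 without NT 6 h replicate 3 or 4 (-1.32 and -1.25, up to 0.106). With chip lot as a block the 3 had limma adjusted p of 0.197, 0.208 and 0.0601, and with extraction day as a block 0.214, 0.102 and 0.0451. The count at 6 h was 3 and 4 with these blocks, 1880 with array weights, 2 with the compared groups fitted alone, 16 without NT 6 h replicate 2, 2 without replicate 3 or 4 and 3 without replicate 5. Within day 2 (2 NT, 4 DDK) 2 probes were called, the higher pair, at fitted log2 differences of 5.32 and 4.10; day 3 holds no DDK array at 6 h.

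At 24 h many more probes differed: 3088 (5.53%), of which 1519 were higher and 1569 lower in DDK, with a median size of 2.13-fold. At an unadjusted limma p under 0.05 there were 15426. E_POPLARS38388P268712 was at least 17.7-fold and E_POPLARS01092P007640, as fitted, 11.4-fold higher. The largest difference downward was that of E_POPLARS16021P112144, a transcript that rose after excision. In NT it went from 7.15 ± 0.25 (SD, n = 5) at 0 h to 8.39 ± 0.56 at 6 h, 11.07 ± 0.16 at 24 h and 10.98 ± 1.26 at 48 h. In DDK it stood at 7.24 ± 0.07 (n = 4), 7.86 ± 0.16, 7.98 ± 0.71 and 9.32 ± 1.01 at the same times. DDK at 24 h was above the controls on 1 of 5 arrays, so the difference was at least 6.09-fold. As fitted it was -3.09 in log2 (SE 0.40, limma adjusted p = 5.14e-05), -2.91 with chip lot as a block (0.0404) and -3.20 with extraction day as a block (0.000618). It was called whichever of its 10 arrays was left out. At 48 h its difference was -1.67 (limma adjusted p = 0.36), and the interaction was not called for this probe. E_POPLARS45506P318541 differed by -2.47 (SE 0.69, limma adjusted p = 0.0381), at least 4.47-fold, with 3 of 5 DDK arrays above the controls. Its call was lost without any of NT 24 h replicates 1 and 2 and DDK 24 h replicates 1, 2, 3 and 5, with differences of -2.66 to -2.10 and limma adjusted p up to 0.146. With chip lot as a block its difference was -0.84, smaller than that bound, which allows for background only. With extraction day as a block it was -2.22.

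The count at 24 h depended strongly on the arrays and the fit. Left out singly, NT 24 h replicates 1, 2, 3 and 4 gave 13, 9, 5492 and 5421 probes, and DDK 24 h replicates 1, 2, 3 and 5 gave 504, 855, 245 and 899. It was 6 with chip lot as a fixed block, 79 with lot as a random block and 62 with extraction day as a block, and 11047 within day 2 (2 NT, 1 DDK) and 3 within day 3 (3 NT, 1 DDK). The only DDK 24 h array of day 2 is replicate 1, which lay far from the rest of its group on component 1 and in the share of probes above the controls, so the 11047 rest on it. Of the probes called in all arrays, 1762 were called within day 2 and 0 within day 3. Median centring gave 12, array weights 1531, the compared groups alone 1692 and ordinary analysis of variance 1344. NT 24 h is also the group with the lowest share of probes above the control probes, 49.1% against 56.8% in DDK 24 h. With that share as a covariate 10 probes were called, and without the 4 arrays under 50%, 5. Over the 3088 probes the median size, 2.13-fold in all arrays, was 1.58-fold with chip lot as a block and 1.63-fold with the share as a covariate. It was 1.65-fold without those 4 arrays, 1.99-fold with extraction day as a block and 1.94-fold with median centring. Within day 2 it was 3.33-fold (log2 1.73), and within day 3 the median log2 size was 0.59, with 96.9% of the probes in the same direction.

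At 48 h, 6 probes differed, 5 higher and 1 lower in DDK (5160 at an unadjusted p under 0.05). E_POPLARS38388P268712 was at least 19.5-fold and E_POPLARS01092P007640, as fitted, 10.9-fold higher. E_POPLARS13672P095704 was at least 2.00-fold lower (limma adjusted p = 0.0135), with 9.37 ± 0.88 (SD, n = 5) in NT and no DDK array above the controls. That call was lost without any of NT 48 h replicates 1 and 3 and DDK 48 h replicates 1, 3 and 5, with log2 differences of -1.63 to -1.37 and limma adjusted p up to 0.125. It was lost too with chip lot as a block (0.649) and with extraction day as a block (0.235). The count was 3 without any of those 5 arrays, 15 without NT 48 h replicate 4, 2 with the compared groups alone, 15 without the 4 arrays under 50%, and 4 with either block. Within day 3 (3 NT, 2 DDK) only E_POPLARS38388P268712 was called, at a fitted log2 difference of 4.72; day 2 holds no NT array at 48 h.

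A score for how far each array had moved from 0 h was formed as the mean log2 change of the probes that rose on average in both genotypes minus that of those that fell, divided by 2. At 24 h it was 1.56 ± 0.10 (SD, n = 5) in NT and 1.36 ± 0.16 (n = 5) in DDK, two-sided exact permutation p = 0.0397, adjusted over the 3 times 0.0834. At 6 h it was 1.33 ± 0.09 and 1.43 ± 0.04 (exact p = 0.0556, adjusted 0.0834), with DDK the higher. With single arrays left out, the exact permutation p at 6 h ran from 0.0079 to 0.111. At 48 h it was 1.46 ± 0.36 and 1.49 ± 0.15 (exact p = 0.897). Without DDK 24 h replicate 1, which scored 1.08, the exact p at 24 h was 0.0714. Each change was taken from the mean 0 h profile of the array's own genotype, so the exact p values leave out the spread of the 0 h arrays. This score was chosen after the other results were seen.

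**Figure D4:**
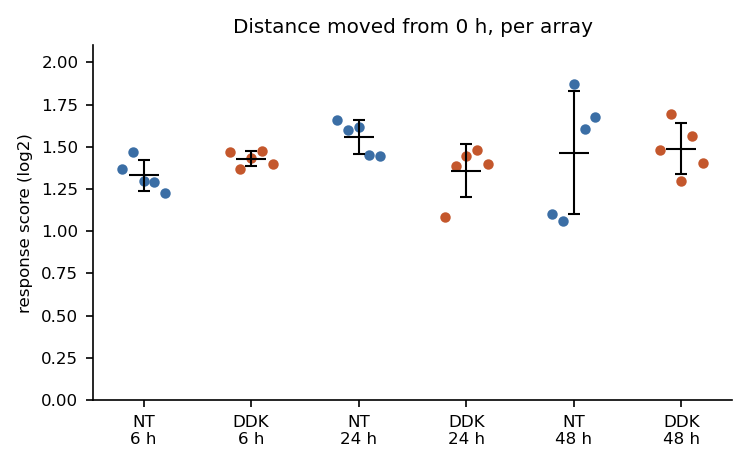
Response score (vertical axis, log2) of each array at 6, 24 and 48 h, by genotype; points are arrays, bars the mean and SD of 5. At 48 h the NT arrays spread from 1.06 to 1.87, more widely than those of DDK, from 1.30 to 1.69.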

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

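These tests were chosen only after the results were seen: chip lot and the response score at 24 h, with its adjustment over times and its left-out arrays, the reference ratios at 24 h, the mislabelled sample and both mixing tests at 0 h, lot, dim arrays and the 6 and 24 h labels at 48 h, and the second probe series.

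Among 92 groups of 4 to 10 arrays examined, 8 held an array far from the others, where chance gives about 4.6. On the first principal component NT 6 h replicate 2 stood at 27.1, with the others between -32.3 and -15.1, and DDK 24 h replicate 1 at 5.14, with the others between 72.4 and 94.2. That DDK array also had the lowest share of probes above the controls in its group, 53.02% against 57.5% to 58.2%. On E_POPLARS38388P268712 NT 0 h replicate 5 read 10.29 (others up to 7.89) and DDK 0 h replicate 3 read 11.59 (others from 12.38). On E_POPLARS01092P007640 NT 0 h replicate 5 read 15.92 (others up to 12.35). E_POPLARS26062P182428 read 14.88 on NT 6 h replicate 2 (others from 15.43), and E_POPLARS01423P009956 read 13.84 on NT 0 h replicate 2 (others from 14.09). The change of E_POPLARS37314P261192 by 24 h differed between genotypes by 2.17 in log2. In the second series of probes, outside the comparisons of the gene model probes, 78.2% exceeded the random controls on most arrays.

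The first pattern weighed is the 3088 probes that differed between genotypes at 24 h, against 2, 5 and 6 at the other times. With chip lot as a block their median log2 size went from 1.09 (quartiles 0.90 and 1.34) to 0.66 (0.51 and 0.82), a ratio of 0.605 (0.549 to 0.642 with each 24 h array left out), and with the share of probes above the controls as a covariate to 0.71 (0.57 and 0.88), a ratio of 0.646 (0.572 to 0.685); 6 and 10 stayed called, because the median absolute t went from 3.55 to 2.13 and 2.47 while the smallest called rose from 3.21 to 5.55 and 5.24. Part of the size goes with them, as lots or shares exchanged at random between arrays left ratios of 0.811 or more and 0.859 or more. The limit of 0.5 set for both tests was wrong, since with the genotype difference at 24 h set to 0 and the residuals of each array given a random sign, the probes then called kept ratios of 0.628 to 0.801 with lot and 0.623 to 0.842 with share (8 and 10 runs of 100 with many calls, of which 0 and 3 reached 3088), so lot and share as the whole cause stay open. A biological candidate explanation, that DDK cuttings were less far along the excision response, had a score difference with exact permutation p = 0.0397, but 0.0834 after adjustment and 0.0714 without DDK 24 h replicate 1, so it stays open too.

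The second pattern is NT 0 h replicate 5, which read high on both probes that part the genotypes. A DDK cutting under an NT label is argued against, since the array lies 1.29 (log2) below the lowest DDK 0 h array on E_POPLARS38388P268712, beyond their SD of 0.41. This rests on 1 probe, as the array read 15.92 on the other, at the level of the DDK arrays. After normalization only 0.00717% of the gene model probes (4, both of these probes among them by construction) deviate upward by as much, so the high readings are not general to this array. Quantile normalization gives all arrays 1 distribution, however, so this cannot decide on a bright array. Its median scanner signal, 1397.78 units, was the highest of all arrays, with the other NT 0 h arrays at 444.78 to 672.22. On E_POPLARS38388P268712 it read 5580.11 units, against 225.78 to 451.11 on those arrays, a wider relative gap than in the medians. This rests on 1 array, and the other probe was saturated there, so brightness stays open. Transgenic RNA mixed into the sample may be the source and stays open: the first probe needs a share of 22.6%, which would give 13.99 on the second, and that read 15.92, saturated. If signals were proportional to amounts, the share from any of the 19 DDK arrays would give at most 14.56, 1.35 below the reading (the second probe alone needs 108.8%), but DDK arrays read near the ceiling on it, so this decides nothing, and no biological explanation was tested.

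The third pattern is the spread of NT 48 h, where replicates 1 and 2 had response scores of 1.10 and 1.06 and the other 3 scored 1.61 to 1.87. Chip lot as the cause is argued against, as replicates 2 and 3 share a lot and differ by 0.81, more than 2 SDs (0.30) of the DDK 48 h scores, and so are dim arrays, as the lowest share of probes above the controls in that pair is 11.9 points above the lowest of the other 3. Samples of 6 h under a 48 h label are argued against, although both arrays lie within the NT 6 h range on component 1, since over the 9505 probes called between 6 and 48 h in DDK both lie 0.82 or more in mean log2 beyond the highest NT 6 h array (SD of these 0.06). Samples of 0 h are argued against by component 1, where both lie 211 or more above the NT 0 h arrays. Samples of 24 h under that label stay open. On component 1 both lie 65.96 or more below the NT 24 h arrays (SD 24.96), but DDK 24 h replicate 1 stood lower still, at 5.14. Over the 1789 probes called between 24 and 48 h in DDK, 1 of the 2 lies only 0.03 beyond the NT 24 h arrays (SD 0.24). Mislabelled time points in general therefore stay open too. Replicate 2 lies nearest to another time of its genotype (NT 6 h, at 0.717 against 0.728 from NT 48 h). The NT 48 h mean leaves the array itself out and so rests on fewer arrays, which adds to that distance. Among all groups both lie nearest to DDK 24 h (0.572 and 0.587), though every NT 48 h array reads 8.64 or less on E_POPLARS38388P268712. Differences in pace between single cuttings were not tested.

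Other splits of the same arrays, 100 drawn for each count with the real one included, show where a count lay beyond those of random groupings. The smallest share they can give is 1 in 100, and no adjustment was made over the counts examined. At 24 h 1 split, the real one, gave as many as 3088 (highest other 708). For the averaged difference 1 gave as many as 18 (highest other 1). The splits therefore argue against chance there but do not exclude it. These splits do not keep chip lot or extraction day, which partly go with genotype at 24 h, so they cannot speak to these batches. With lot as a block 6 probes were called at 24 h, and the median log2 size of the 3088 went from 1.09 to 0.66. With day as a block 62 were called, but that size went only to 0.99 and 100% kept their direction. The splits argue against chance for the changes against 0 h as well, with 1 split each. In NT 13960, 22959 and 20607 were called at 6, 24 and 48 h against 5738, 14979 and 15115 at the highest. In DDK 14152, 16873 and 18507 were called against 10020, 15308 and 17131. Chance stays open for the genotype counts at 0 h (2 probes, 6 splits, highest other 37), 6 h (5 probes, 7 splits, highest 1970) and 48 h (6 probes, 15 splits, highest 6925). A split counts calls whatever the probe, so these results do not speak to the 2 probes called at all 4 times. For the interaction the real count is 0, so all 100 splits give as many by construction (highest 831) and the comparison decides nothing. The split with 6925 exchanges DDK 48 h replicates 2 and 5 with NT 48 h replicates 1 and 2, and the one with 1970 sets NT 6 h replicate 2 and DDK 6 h replicates 1 to 4 against the rest. Both call far more than the real count, which points to a structure of the samples other than genotype. The latter parts the arrays by extraction day but for NT 6 h replicate 1, and the highest split at 0 h sets 4 arrays of extraction day 2 against a group with 1 array of that day; with day as a block the real counts were 4 at 6 h and 2 at 0 h.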

How the results depend on the processing

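The fits within a day, with day as a block, with the share of probes above the controls as a covariate, and without arrays under 50% were chosen after seeing the data. No named difference reversed, while in time comparisons the share of probes upward crossed 50% with median centring (NT 6 h, 45.8% to 59.5%; NT 24 h, 46.6% to 57.5%; NT 48 h, 46.9% to 56.6%; DDK 24 h, 48.8% to 62.8%) and from 24 to 48 h in NT without arrays under 50% (72.6% to 45.9%). In DDK it did so with lot as a fixed block, from 53.6% to 41.5% for 6 to 24 h and from 47.4% to 77.5% for 24 to 48 h, and with day as a block (45.4% and 58.1%). The time counts against 0 h stayed within 1.5 times under every setting but these: within day 2, DDK 24 h gave 7828, and within day 3, DDK 24 h gave 7715 and DDK 48 h 9497, from fewer arrays. The correlations of the time courses stayed within 1 jackknife SD in every setting. Genotype counts moved as follows, at 0 h from 2, at 6 h from 5, at 24 h from 3088, at 48 h from 6, on average from 18 and for the interaction from 0. No background correction gave 6 at 0 h and 1 for the interaction. Removal of dim probes gave 4 at 0 h. Median centring gave 12 and ordinary analysis of variance 1344 at 24 h. Array weights gave 11 at 0 h, 1880 at 6 h, 1531 at 24 h, 34 on average and 276 for the interaction. Lot as a random block gave 4 at 0 h and 79 at 24 h, and as a fixed block 3 at 6 h, 6 at 24 h and 9 on average. The compared groups alone gave 0, 2, 1692 and 2 at 0, 6, 24 and 48 h, from fewer arrays. Day as a block gave 62 at 24 h and 8 on average. The covariate gave 4 at 0 h and 10 at 24 h. Without arrays under 50% there were 5 at 24 h and 15 at 48 h. Within day 2 there were 2 at 6 h and 11047 at 24 h, and within day 3 0, 3 and 1 at 0, 24 and 48 h. Where no reason is given, the cause was not tested.

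Leaving out each array gave 2 to 5 at 0 h, 2 to 16 at 6 h, 9 to 5492 at 24 h, 3 to 15 at 48 h, 10 to 24 on average and 0 to 3 for the interaction. For NT it gave 12708 to 13500, 20420 to 23051 and 17592 to 21997 at 6, 24 and 48 h, and for DDK 12508 to 13924, 15187 to 17169 and 16494 to 18934. The correlations ran from 0.881 to 0.937 at 6 h, 0.886 to 0.929 at 24 h and 0.918 to 0.952 at 48 h. Of 384 alternative values of the 32 named differences, 358 kept their direction and call, 26 kept the direction only and 0 reversed.

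Over all gene model probes, median centring moved the differences by a median log2 of 0.26 for the genotypes at 24 h, 0.20 for DDK at 24 h and 0.18 for NT at 6 h. No paired analysis was possible because the labels do not number the replications. The gene list tests were not run, as no table used here names the probes. Within day 1 or 4, and for the averaged and interaction tests within any day, groups are missing. Signal over background limits what can be seen: from 43.7% to 65.2% of the probes exceeded the controls. A log2 change of 1 was recovered in 28% of simulated cases at 0 h and 42% at 24 h. The simulation held no lot, day or array-wide structure.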

Other observations

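The comparisons of successive times, the shapes over time and the tests of the second probe series were added after seeing the data. In the non-transgenic stem base 28685 probes (51.4%) were called at 1 or more times after excision, and in DDK 23903 (42.8%). Among the changed probes a lasting change was frequent: 9876 probes in NT and 9757 in DDK moved the same way at all 3 times. Within a genotype the 3 changes share their 0 h arrays, which favours this shape, and no split control was run for it. Of these, 4096 rose and 5780 fell in NT, and 8331 had this shape and direction in both genotypes. A brief early change was seen too, with 1136 probes raised and 784 lowered at 6 h alone in NT, of which 454 and 304 had that shape in DDK as well, where independent lists would share 22.1 and 14.5. Opposite directions at different times were called for 650 probes in NT and 374 in DDK. In NT 253 probes rose at 6 h and lay below their 0 h level at 24 and 48 h, in DDK 93 did, and 59 did so in both, against 0.42 for independent lists. Each shape rests on calls, so a probe near the threshold can move from one shape to another.

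Between 6 and 24 h 15531 probes changed in NT (7107 upward) and 8849 in DDK (4746 upward). Between 24 and 48 h 1925 changed in NT (1397 upward) and 1789 in DDK (848 upward). For the changes from 6 to 24 h, 1 split of 100, the real one, gave as many calls (highest other 14004 in NT and 3174 in DDK). For 24 to 48 h this was 1 in DDK (highest other 279), but 5 in NT (highest other 3702), so chance is not excluded there. With chip lot as a block the 4 counts were 17785, 7052, 686 and 80, in the order NT and DDK from 6 to 24 h and NT and DDK from 24 to 48 h. With extraction day as a block they were 17150, 6191, 792 and 1004. Other settings that moved a count were these. From 24 to 48 h NT gave 31 with the compared groups alone, 183 (45.9% upward) without arrays under 50%, 665 with the share as a covariate, 695 with array weights and 1053 with median centring. DDK gave 1009 with the compared groups alone, 2888 with array weights and 865 with lot as a random block. From 6 to 24 h NT gave 7732 without arrays under 50%, and DDK 13820 with array weights. Within day 2 the counts from 6 to 24 h were 8573 in NT and 3781 in DDK, and from 24 to 48 h 7155 in DDK. Within day 3 they were 10814 in NT from 6 to 24 h, and 149 in NT and 9 in DDK from 24 to 48 h. The NT count from 24 to 48 h was 823 without NT 24 h replicate 1 or 2, 3420 without replicate 3, 1174 without NT 48 h replicate 1 and 4135 without NT 48 h replicate 4. The DDK count was 629 and 1011 without DDK 24 h replicates 1 and 2, and 822 and 796 without DDK 48 h replicates 1 and 2. Median centring changed the share upward from 45.8% to 26.2%, 53.6% to 75.6%, 72.6% to 92.4% and 47.4% to 36.3% in the same order.

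The arrays carry a second series of 12084 probes whose numbers repeat those of gene model probes. A hypothesis was that the same transcript is read by a second probe. The median correlation over arrays between probes that share a number was 0.712, above the highest of 100 random pairings (-0.0006), as this hypothesis predicts, and it is consistent with a common transcript for most pairs, though 8.26% of the pairs correlated below 0. The series showed the same course, with 4190, 6367 and 5912 probes changed in NT at 6, 24 and 48 h. Of the probes called at 6 h in both series, 3125 moved the same way and 13 the opposite way in NT. Between genotypes limma called 0 of the second series at 0, 6 and 48 h (100, 552 and 1314 at an unadjusted p under 0.05), 442 at 24 h and 1 on average. At 24 h 701 of the partner gene model probes were called, and 125 pairs were called in the same direction in both series and 1 in opposite directions (r of the differences 0.58).

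Each array was also compared with the mean profile of every group, itself left out. The nearest group had the right time for 34 of 39 arrays and the right genotype for 21, and it was the array's own group for 19. The mean of the own group rested on fewer arrays than the group holds, while the other means were complete. A mean of fewer arrays lies farther off, which in most groups works against the own genotype. These counts therefore do not tell how far the genotypes can be told apart. The right genotype was nearest for 0, 4, 4 and 3 of 5 NT arrays at 0, 6, 24 and 48 h. In DDK this held for 0 of 4 arrays at 0 h and for 3, 5 and 2 of 5 at 6, 24 and 48 h. At 48 h the nearest group had the right time for 2 of 5 NT arrays and 4 of 5 DDK arrays.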
